A study of Homo sapiens with 20 samples.

How the data were processed

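Total RNA from U2OS cells was amplified, labelled with biotin and hybridized to Affymetrix 3' expression arrays, per the labels' protocols. The deposited table holds 1 intensity per probe set and array, 54675 probe sets on 20 arrays, on a linear scale with no missing value. The authors made these intensities with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, normalizes between arrays and summarizes probes, and the deposited quartiles were close but not equal between arrays (upper quartile 162.4 to 200.9). A change shared by most transcripts, such as the loss of mRNA after DRB, is therefore removed, and every level and slope is relative to the array's typical transcript. RMA gives no call of presence, so the lowest signals (from 5.28) mark a floor rather than absence. All 20 value columns were matched to samples by the labels. The arrays' pairwise Pearson correlations over probe sets were 0.930 to 0.996.

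Values were transformed to log2. Probe sets were named from the platform annotation, with symbols updated through Entrez gene identifiers to a RefSeq gene table. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and were not named, and 11777 had none. After 6 control probe sets were set aside, 41091 probe sets with 1 symbol covered 19775 genes. Each gene was represented by its probe set with the highest mean over all arrays, and genes whose mean lay above the 40th percentile of all probe sets (log2 4.70) were tested, 14478 in all. Detection calls were not analysed here, so the size of a change from control signals around or below this value is uncertain. Genes without a single-symbol probe set above this level, GAS5 among them, were not analysed here. Probe sets that end in _s_at or _x_at may detect several transcripts or cross-hybridize.

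Groups were taken from the treatment label and times from the sampling label. The main model was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes): time as a factor, condition, and a linear time term per condition, 12 coefficients with 8 residual degrees of freedom. It gives for each condition the level difference from control at DRB addition and the slope difference in log2 per hr, positive where a transcript fell more slowly or rose more than in control. The slope of control itself came from a model with a line per condition, 10 coefficients with 10 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. They measure only the scatter of single arrays about the lines. Nothing in the labels says that arrays came from separate cultures, and culture or array batch cannot be told apart from condition.

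Gene lists were fixed before the data were examined: 18 lists with 538 entries, of which 457 had a probe set with 1 matched symbol. The others had none in the annotation used or only probe sets with several symbols, and GARS, SARS and NDUFA4 were left unmatched because these older symbols belong to more than 1 gene. They covered NMD factors, stress transcripts known or proposed as NMD targets, snoRNA host genes, splicing factors with poison exons, integrated stress response, ER unfolded protein response, HIF targets, immediate early and AU-rich transcripts, p53 targets, ribosomal proteins, oxidative phosphorylation, histones, mitosis, cholesterol synthesis, heat shock, interferon-stimulated genes, mesenchymal genes, and markers of other cell types. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 72 tests of levels or of slopes (90 for slopes within conditions). Counts of members past the test use the adjustment over all genes unless the text says that p was adjusted over the list alone. Genes named in the text follow a rule fixed before the data were examined: per comparison with control, the 5 highest and 5 lowest estimates past the threshold (filled by the largest moderated statistics where fewer passed), the 3 members with the largest statistics of lists assigned to the condition, and UPF1, ATF4, ATF3, DDIT3, GADD45A, GADD45B and GAS5; for control, the 10 lowest and 5 highest slopes and 3 members of 4 lists. A gene that this rule names is left out of the text, for a reason unrelated to its values. ATF3, GADD45A and other members given for the first interval after DRB, and genes named in the closing section, were named after their values were seen where this rule does not hold them.

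Beside a fitted level, the measured difference of the arrays at 0 hr is a value without a test. The fits were tested on simulated data with the real time means and residual spread, with 200 of 14478 genes changed. A slope difference of 0.4 log2 per hr was recovered for 97 of 100 genes in hypoxia, 99 in tunicamycin, 95 in emetine and 94 in UPF1-depleted cells, and one of 0.2 for 61, 37, 50 and 46. A level difference of 1 was recovered for 94, 92, 96 and 89 of 100 genes, and one of 0.5 for 34, 32, 33 and 27. Of unchanged genes, 2 to 11 were called per simulated comparison. The added slope changes were linear in time and placed in genes drawn at random. Over all genes the median SE of a slope difference was 0.049, against 0.16 for ATF3 and 0.21 for GADD45B. These rates therefore do not apply to transcripts with such scatter or a curved course, for which a missed call does not show that a change was absent. Alternatives fixed beforehand were a straight line per condition with no common time factor, only the arrays compared, no filter and a 60th percentile filter, centring on ribosomal protein genes, quantile normalization, the median of a gene's probe sets, leaving out _s_at and _x_at probe sets, eBayes with trend and robust options, leaving out the 0 hr or 4.5 hr arrays, the mean level over the 4 times, and leaving out each compared array in turn. A filter on the mean of the control arrays, and 3 alternatives for slopes compared between conditions, were chosen after seeing the data. Shared controls were simulated 20 times, and random lists matched on mean signal were drawn 10000 times. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.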

Results

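Messenger RNA was profiled in U2OS, an established human osteosarcoma cell line, with 3' expression microarrays holding 54675 probe sets. The 20 arrays fall into 5 conditions of 4 arrays each: control cells, cells exposed to hypoxia (below 0.1% oxygen), cells given tunicamycin (2.5 ug/ml), cells given emetine (100 ug/ml), and cells depleted of UPF1, written shRent1 in the labels. The stresses lasted 3 hr. Tunicamycin blocks N-linked glycosylation and so loads the endoplasmic reticulum (ER) with misfolded protein. Emetine stops translation elongation, and UPF1 (also called Rent1) is the RNA helicase at the core of nonsense-mediated mRNA decay (NMD). Transcription was then blocked with DRB (100 ug/ml), which stops elongation by RNA polymerase II, and RNA was taken at 4 times, from 0 to 4.5 hr at steps of 1.5 hr. Each condition and time has 1 array, so no time point has a replicate, and the error of every estimate is the scatter about fitted lines. The labels name no control hairpin for the UPF1-depleted cells and do not say whether a stress continued during DRB. The median signal per array ran from 37.3 to 40.4 and the number of arrays limits the precision. After normalization between arrays, a slope says how a transcript moved relative to the typical transcript of its array, not its absolute half-life.

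UPF1 was lower in the depleted cells at every time. Its brighter probe set read 354.5, 352.4, 392.2 and 377.0 in control cells and 169.5, 92.4, 94.7 and 89.4 in depleted cells, from 0 to 4.5 hr. The mean over the 4 times was 29.1% of control (log2 difference -1.78 ± 0.48, SD over 4 times). A dimmer probe set gave 61.0% of control, with 4 of 4 arrays lower. In the model of all arrays the level of UPF1 at DRB addition was lower by a log2 difference of -1.31 ± 0.16 (SE; limma adjusted p = 0.000324), against a measured difference of -1.06 between the arrays at 0 hr. In the other conditions the brighter probe set averaged 89.2% of control in hypoxia, 105.0% in tunicamycin and 126.7% in emetine, and the dimmer 94.1%, 100.8% and 100.3%.

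**Figure D1:**
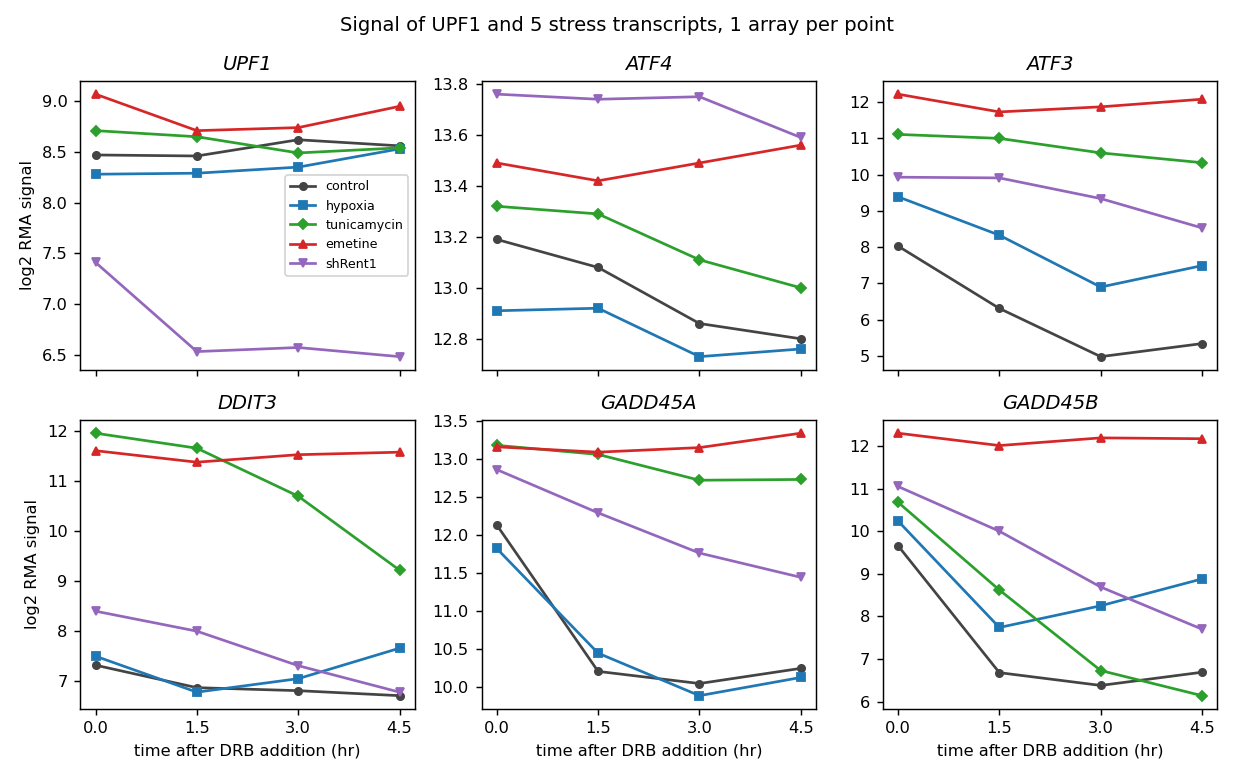
Log2 signal of UPF1 and of 5 stress-responsive transcripts against hours after DRB, 1 line per condition and 1 array per point, without error bars because no time has a replicate. UPF1 is lowest in depleted cells at all 4 times, and ATF3 falls by 1.73 on the log2 scale within 1.5 hr in control cells against 0.02 in depleted cells.

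The first comparison asks which transcripts were lost after DRB in unstressed cells. Among the steepest falls were those of SGK1, a serum- and stress-regulated kinase (-1.19 ± 0.18 log2 per hr, SE), PLK2, a stress-induced Polo-like kinase (-1.18 ± 0.14), TRMT10C (-1.15 ± 0.10) and CLK1, a kinase of splicing factors (-1.09 ± 0.14). CLK1 read log2 3.68 at 3 hr and 3.51 at 4.5 hr, and SGK1 4.61 at 3 hr, below the filter value. The sizes of these 2 slopes are therefore uncertain. MPHOSPH10, ZBED5, TIFA, EIF1AD and the mitotic inhibitor WEE1 followed, with slopes from -1.08 to -0.99. Of 43 measured immediate early and AU-rich transcripts, 22 fell and 0 rose, among them BTG1 (-0.70 ± 0.05), ZFP36L2 (-0.66 ± 0.06) and ID2 (-0.95 ± 0.09). Of 20 p53 targets, 10 fell, CDKN1A at -0.36 ± 0.04, and 1 rose. Of 29 mitotic genes 19 fell, of 23 splicing factors 11 fell and 1 rose, of 34 integrated stress response genes 10 fell and 3 rose, and of 14 stress transcripts that are known or proposed NMD targets 10 fell. Oxidative phosphorylation genes went the other way: 13 of 42 rose relative to the array, such as ATP5F1D at 0.12 ± 0.03, and 1 fell. Ribosomal protein transcripts barely moved, with 1 of 51 rising (RPL36, 0.07 ± 0.02). The largest relative increases were RASSF10 (0.98 ± 0.20), LINC00942, LINC00926, FRMD3 and RPPH1, the RNA of RNase P (0.44 ± 0.05). RASSF10 (log2 3.68 and 3.74) and LINC00942 (3.78 and 3.94) read below the filter value at 0 and 1.5 hr, and FRMD3 (4.14) at 0 hr. At 4.5 hr so did ID2 (3.85), EIF1AD (4.66) and BTG1 (4.69). The sizes of these slopes are uncertain too.

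In all, 4592 of 14478 genes had a control slope different from 0 at an adjusted p under 0.05 (limma), 2529 falling and 2063 rising. The lists of immediate early, mitotic, p53, splicing, integrated stress response and NMD target genes fell and that of oxidative phosphorylation genes rose in camera's test (adjusted p from 7.28e-09 to 0.0254), and none of these list calls held with an estimated correlation (adjusted p = 0.306 or more). Adjusted over the list alone, 24 immediate early and 15 oxidative phosphorylation genes passed in these directions. The count rests on the ends of the time course: it was 1492 without the control array at 0 hr and 2442 without that at 4.5 hr, and only 9.7% of the former and 33.9% of the latter rose, against 44.9% with all arrays. The rising share was 30.5% with arrays centred on ribosomal protein genes and 59.6% after quantile normalization, and RPL36 did not pass with the former (adjusted p = 0.0789). Without the array at 0 hr, the calls of SGK1 (-0.74, adjusted p = 0.0663; -1.80 without that at 4.5 hr), LINC00926 (0.0828) and FRMD3 (0.25; 0.177) were lost, without that at 4.5 hr that of LINC00942 (0.0687), and without either those of RPL36 (0.04 without that at 0 hr), ATP5F1D and NDUFB1 (highest adjusted p = 0.553). The slope of ZBED5 was 0.14 (adjusted p = 0.0204) and that of NDUFB1, which rose at 0.11 ± 0.02, was -0.29 (adjusted p = 0.0329) when probe sets that may cross-hybridize were left out.

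**Figure D2:**
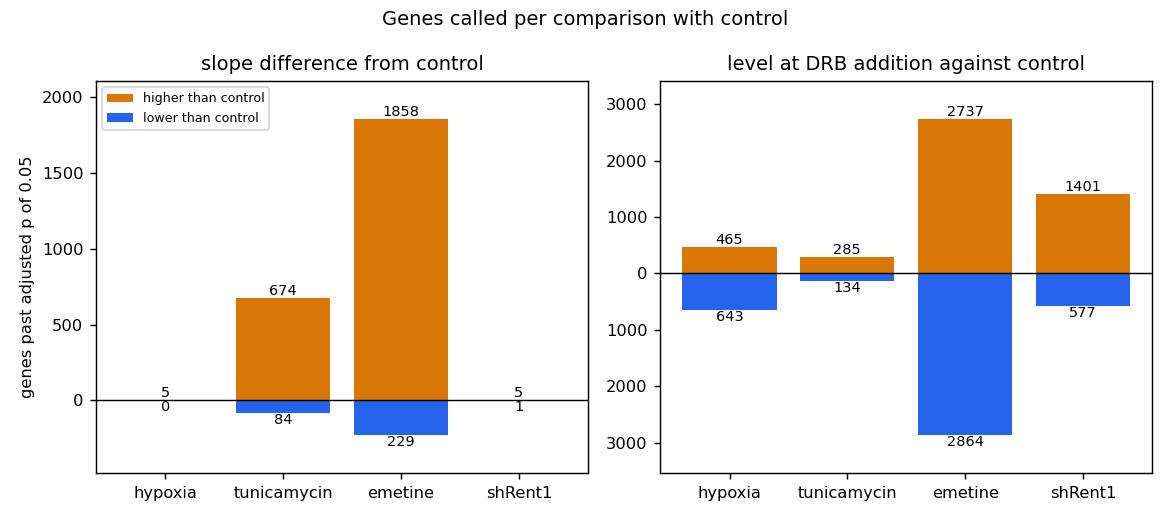
Number of genes past an adjusted p of 0.05 (vertical axis) in each comparison with control, bars above 0 for higher and below 0 for lower estimates; left, slope after DRB, right, level at DRB addition. Emetine changed most genes in both, and hypoxia and UPF1 depletion changed 5 and 6 slopes against 1108 and 1978 levels.

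Hypoxia was compared with control first for the level at DRB addition, that is, after 3 hr below 0.1% oxygen. Targets of the hypoxia-inducible factors rose together: 34 of 43 measured members passed the test upward and 0 downward, with a median log2 difference of 1.20. DDIT4, an inhibitor of mTOR signalling, was 23.2-fold higher (log2 4.54 ± 0.46, SE; measured difference at 0 hr 4.77), PFKFB4, a regulator of glycolysis, 10.4-fold, and the glucose transporter SLC2A3 9.27-fold. The kinase PDK1, which holds back pyruvate oxidation, was 6.82-fold higher (2.77 ± 0.20) and the oxygen sensor EGLN1 3.84-fold (1.94 ± 0.15). The vasodilator peptide gene ADM (3.65 ± 0.62) and, outside the list, PPP1R3C, which targets a phosphatase to glycogen (3.68 ± 0.35), also rose. Control signals of both fell to between log2 4.47 and 4.97 after 0 hr, around the filter value of 4.70. Without the hypoxia array at 0 hr the log2 differences were 3.54 for DDIT4, 2.62 for ADM, 2.74 for PFKFB4 and 2.62 for PPP1R3C, and without the control array at 0 hr that of ADM was 4.79. The lowest estimates were those of ODAPH (-2.56 ± 0.20), the chemokine CCL4 (-1.99 ± 0.12), KRT75 (-1.90 ± 0.18), TMEM165 (-1.62 ± 0.16) and the protease MMP9 (-1.55 ± 0.14). In hypoxia ODAPH read log2 4.27 to 4.77, around the filter value, so the size of its difference is uncertain. At 0 hr KRT75 and MMP9 read 7.55 and 11.94 in control and 7.22 and 11.79 in tunicamycin. They read 5.71 and 10.31 in hypoxia and 5.42 and 9.92 in emetine, so their lower signals were not particular to hypoxia. The ER list had 1 member higher and 5 lower of 35, and the integrated stress response list 3 higher and 3 lower of 34, with SLC3A2 (-0.66 ± 0.13) and AARS1 (-0.41 ± 0.09) among the lower.

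None of the 14 NMD target transcripts passed for its level in hypoxia. ATF3, a stress-induced transcription factor, had the largest estimate (1.52 ± 0.44, adjusted p = 0.0569; 0.0394 and 0.0363 without the hypoxia array at 3 and 4.5 hr; 0.00264 to 0.726 over the alternatives), ATF4 gave -0.26 ± 0.10, DDIT3 -0.08 ± 0.32, GADD45A -0.11 ± 0.34, and GADD45B 0.58 ± 0.58. The snoRNA host EPB41L4A-AS1 rose (0.79 ± 0.19, adjusted p = 0.0251), though not without the hypoxia array at 0 hr or 1.5 hr or the control array at 1.5 hr (highest adjusted p = 0.214), and with 1.43 without the control array at 0 hr.

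Hypoxia changed the level of 1108 genes, 465 upward and 643 downward (limma, adjusted p under 0.05). The HIF target list passed camera's test (adjusted p = 4.17e-40) and held with an estimated correlation (adjusted p = 0.0191). The immediate early (3 of 43 higher, 1 lower) and mitotic (2 of 29 higher) lists passed camera's test upward (adjusted p = 0.00711 for both) but not with an estimated correlation (adjusted p = 0.553 for both). Adjusted over the list alone, 37 members of the HIF target list passed. The count of changed levels fell to 87 without the control array at 0 hr and to 77 without the hypoxia array at 0 hr. The level at 0 hr is then extrapolated, and whether this or an unusual array lowered the count was not tested. ADM did not pass without the hypoxia array at 0 hr, and SLC3A2 and AARS1 without either of the 0 hr arrays (highest adjusted p = 0.426). Signal at the 3' end of ACTB exceeded that at its 5' end by a log2 ratio of 2.04 ± 0.13 (SD of 4 arrays) in hypoxia and 0.55 ± 0.10 in control.

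After DRB, 5 transcripts had a higher slope in hypoxia than in control: GJC1, a connexin (slope difference 0.32 ± 0.04 log2 per hr, SE), the chromatin remodeller CHD1 (0.29 ± 0.04), PWWP2A (0.28 ± 0.04), C5orf34 (0.28 ± 0.04) and CCDC93 (0.25 ± 0.03), with adjusted p from 0.0332 to 0.0386. Within hypoxia, CCDC93 and PWWP2A rose relative to the array, with slopes of 0.163 and 0.103 log2 per hr. GJC1 (-0.17), CHD1 (-0.183) and C5orf34 (-0.233) fell more slowly than in control. No transcript passed in the opposite direction, where RAB20 had -0.43 ± 0.07 (adjusted p = 0.0672; 0.044 without the hypoxia array at 1.5 hr). Across transcripts chosen because they fell in another condition, the UPF1-depleted cells (2389 genes), the median slope was -0.17 in hypoxia, 78.4% of the control value. Of the NMD targets, MAP3K14 had 0.23 ± 0.07, NAT9 0.13 ± 0.04, ATF3 0.15 ± 0.16, DDIT3 0.18 ± 0.11, GADD45A 0.01 ± 0.12, and GADD45B 0.38 ± 0.21, none of which passed. From 1.5 to 4.5 hr in hypoxia, DDIT3 and GADD45B rose by 0.89 and 1.14, as did EGR1 (1.58) and FOS (2.34, from log2 4.11). ATF3 (-0.83), MAP3K14 (-0.82) and GADD45A (-0.32) fell. A higher slope in hypoxia therefore need not mean a slower loss. The ER list had a median slope difference of 0.08 with 0 of 35 members past the test (1 adjusted over the list alone). It passed camera's test (adjusted p = 4.8e-06) but not with an estimated correlation (adjusted p = 0.566). The immediate early (adjusted p = 0.0212) and cholesterol (0.0406) lists also passed upward with 0 members past the test, and neither held with an estimated correlation (adjusted p = 0.686 and 0.679). At an unadjusted p under 0.05 there were 1498 genes. The 5 calls are fragile: without 1 array in turn the count ran from 0 to 7, with 0 without the control array at 0 or 4.5 hr or the hypoxia array at 3 or 4.5 hr and 1 without the hypoxia array at 0 hr. It was 24 with the filter at the 60th percentile, 25 with that on control means and 54 with trend and robust eBayes. None passed with arrays centred on ribosomal protein genes (adjusted p from 0.0598 to 0.0737).

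Tunicamycin raised the transcripts of ER and amino acid stress. Of 35 measured unfolded protein response genes 16 rose and 0 fell, including HERPUD1, a component of ER-associated degradation (7.62-fold; log2 2.93 ± 0.11, SE), the chaperone HSPA5 (3.82-fold), its co-chaperone DNAJB9 (log2 3.30 ± 0.26, with control signals down to 4.42) and DNAJC3 (3.09-fold). Of 34 integrated stress response genes 18 rose and 0 fell. DDIT3, the pro-apoptotic factor CHOP, was 33.2-fold higher (5.05 ± 0.32; measured difference at 0 hr 4.64), DDIT4 30.2-fold (4.92 ± 0.46) and SESN2, a sestrin, 15.3-fold (3.93 ± 0.24). Of the 14 NMD targets 8 rose: ATF3 12.1-fold (3.60 ± 0.44; 3.08 measured at 0 hr), GADD45A, a DNA damage-inducible gene, 3.14-fold (1.65 ± 0.34, adjusted p = 0.0236; 1.05 measured at 0 hr) and UPP1, uridine phosphorylase, 1.89-fold. ATF4 (0.16 ± 0.10) and GADD45B (1.64 ± 0.58, adjusted p = 0.163) did not pass. The snoRNA hosts EPB41L4A-AS1 (2.20-fold) and ZFAS1 (1.52-fold) rose, and SNHG4 had 0.09 ± 0.18. Without the control array at 0 hr the log2 differences were 4.53 for ATF3, 2.75 for GADD45A and 1.78 for EPB41L4A-AS1, and without the tunicamycin array at 0 hr 6.06 for DDIT3 and 2.30 for GADD45A. ODAPH (-1.64 ± 0.20), ZBED2, the complement inhibitor CD59, TMEM165 and the chemokine CCL2 (-1.19 ± 0.20) were lowest.

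In all, tunicamycin changed 419 levels, 285 upward and 134 downward (limma). The integrated stress response, ER and NMD target lists passed camera's test (adjusted p = 2.46e-30, 7.21e-20 and 3.63e-16) and held with an estimated correlation (adjusted p = 0.000175, 0.0171 and 0.0171). Adjusted over the list alone, 23, 18 and 11 members passed. The immediate early (adjusted p = 1.79e-10; 7 of 43 higher, 1 lower), HIF target (1.13e-05; 4 of 43 higher), snoRNA host (0.00366; 2 of 4 higher) and p53 (0.0105; 4 of 20 higher, 1 lower) lists passed camera's test upward and the oxidative phosphorylation list downward (0.000404; 0 of 42 called), none with an estimated correlation (adjusted p = 0.139 or more). The count was 93 without the control array and 88 without the tunicamycin array at 0 hr. Without 1 array, GADD45A lost its call in 4 cases (control at 4.5 hr; tunicamycin at 0, 1.5 or 4.5 hr; highest adjusted p = 0.0807), and CCL2, CD59, ODAPH, TMEM165, UPP1 and ZFAS1 without the control array at 0 hr (highest adjusted p per gene from 0.0555 to 0.275). Without the tunicamycin array at 0 hr, CCL2, ODAPH and EPB41L4A-AS1 (adjusted p = 0.0901) did not pass. The ACTB end ratio, 0.54 ± 0.11, lay within the control range, and TMEM165 had 0.07 with the median of its probe sets.

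**Figure D3:**
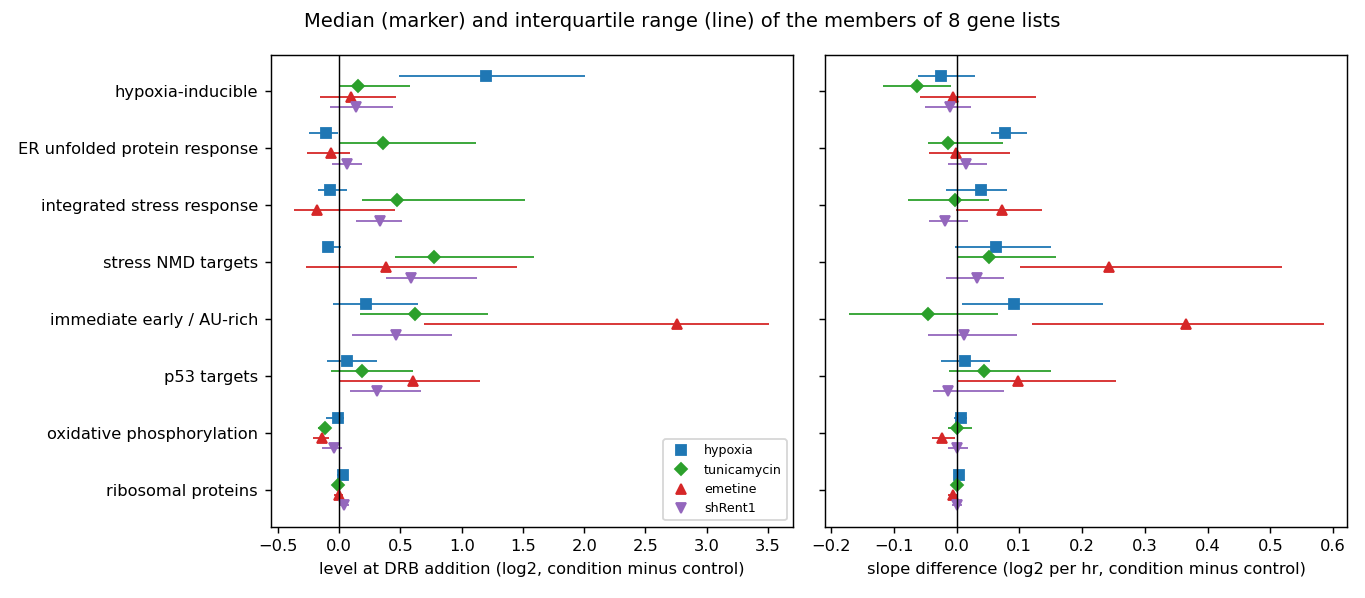
Median (marker) and interquartile range (line) over the members of 8 gene lists, for the level at DRB addition (left, log2) and the slope difference (right, log2 per hr), each condition minus control. HIF targets stand at 1.20 in hypoxia, integrated stress response genes at 0.47 in tunicamycin, and immediate early genes at 2.76 for level and 0.37 for slope in emetine.

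After DRB, the slope was higher in tunicamycin than in control for 674 transcripts and lower for 84. Among the largest positive slope differences were those of TIFA (0.89 ± 0.11 log2 per hr, SE), XBP1, a transcription factor of the unfolded protein response (0.76 ± 0.11), MTFR2 (0.71 ± 0.08) and BRIX1 (0.62 ± 0.08). XBP1 fell at -0.91 ± 0.09 in control and had -0.15 ± 0.09 in tunicamycin. Among the lower slopes were those of genes whose level tunicamycin had raised: DDIT4 (-0.94 ± 0.16), CHAC1, which degrades glutathione (-0.86 ± 0.10), SESN2 (-0.63 ± 0.09), DDIT3 (-0.49 ± 0.11) and PNRC1 (-0.42 ± 0.06). Of 34 integrated stress response genes 3 had higher and 4 lower slopes, TRIB3 among the higher (0.33 ± 0.04). Of 14 NMD targets 1 had a higher slope (NAT9, 0.16 ± 0.04, adjusted p = 0.0436) and 1 a lower one (DDIT3); NAT9 did not pass under either other scaling of the arrays (adjusted p = 0.0726 and 0.121). ATF3 had 0.45 ± 0.16 (adjusted p = 0.149; 0.0216 to 0.957 over the alternatives), GADD45A 0.28 ± 0.12, and GADD45B -0.42 ± 0.21. EPB41L4A-AS1 had a higher slope (0.33 ± 0.07).

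Of the 2389 transcripts that fell in depleted cells, the median slope was -0.13 in tunicamycin, 60.3% of that in control. The slope of the mitotic list was higher (3 of 29 members past the test, 10 adjusted over the list alone; camera adjusted p = 8.54e-06) as was that of the splicing factor list (4 of 23; 0.0375), and those of the HIF target (1 of 43; 0.000176) and mesenchymal (0 of 13; 0.00602) lists were lower. None held with an estimated correlation (adjusted p = 0.608 or more). The 758 calls became 173 without the control array at 0 hr, 390 without that at 4.5 hr, 141 without the tunicamycin array at 0 hr and 245 without that at 4.5 hr. DDIT3 (without the array at 4.5 hr of either condition or the control array at 0 hr; highest adjusted p = 0.415), NAT9, XBP1, DDIT4, PNRC1, SELENOS, HERPUD1 and EPB41L4A-AS1 lost their calls in 2 to 6 of 8 such fits. The slope differences were 0.10 for NAT9 and 0.15 for EPB41L4A-AS1 without the control array at 0 hr, and that of DDIT3 was -0.77 without the tunicamycin array at 0 hr and -0.23 without that at 4.5 hr. For HERPUD1 the direction depended on the probe set: 0.19 ± 0.04 for the brightest, and -0.53 (adjusted p = 0.0341) without possibly cross-hybridizing probe sets.

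Emetine changed the levels of more genes than any other condition, 2737 upward and 2864 downward at DRB addition. Of 43 measured immediate early transcripts 33 rose and 3 fell, with a median log2 difference of 2.76, though the list did not pass camera's test with an estimated correlation (adjusted p = 0.136). EGR1 was 43.0-fold higher, ZFP36, whose protein destabilizes AU-rich mRNA, 27.0-fold (4.76 ± 0.15, SE), and the chemokine CXCL8 7.51-fold. At 0 hr EGR1 read log2 14.51 in emetine and 9.85 in control, a smaller difference than the fitted 5.43. FOS (7.74 ± 0.49; measured difference at 0 hr 7.58) and FOSB (4.82 ± 0.29) rose from control signals around the filter value of log2 4.70, between 4.11 and 4.88 and between 4.58 and 4.90. CREBRF rose 31.8-fold. Of the 14 NMD targets 8 rose and 4 fell: ATF3 21.7-fold (4.44 ± 0.44), DDIT3 19.8-fold (4.31 ± 0.32), GADD45B 11-fold (3.47 ± 0.58; 2.64 measured at 0 hr), GADD45A 2.97-fold, CDKN1A 2.12-fold and ATF4 1.20-fold. GADD45A read log2 13.16 in emetine and 12.13 in control at 0 hr, a smaller difference than the fitted 1.57. EPB41L4A-AS1 rose 5.20-fold and ZFAS1 2.08-fold, whereas SNHG4 fell (-0.61 ± 0.18). Of 11 replication-dependent and related histone genes 7 rose, H2AC6 2.97-fold, and of 15 cholesterol synthesis genes 9 rose. Without the emetine array at 0 hr the log2 differences were 8.63 for FOS, 6.65 for EGR1, 4.48 for GADD45B, 3.84 for FOSB and 0.90 for H2AC6. Without the control array at 0 hr they were 6.44 for EGR1, 5.38 for ATF3, 4.86 for GADD45B, 3.02 for EPB41L4A-AS1 and 2.67 for GADD45A. The brighter UPF1 probe set was 1.37-fold higher (adjusted p = 0.0405), whereas the dimmer averaged 100.3% of control over the 4 times with 2 of 4 arrays lower. RGS4, a regulator of G-protein signalling (-3.80 ± 0.23), BCL2A1, an anti-apoptotic gene (-3.73 ± 0.30), SPOCD1, CCL4 and PCDH7 were lowest. In emetine BCL2A1 read log2 4.19 to 4.58, below the filter value, so the size of its difference is uncertain. After DRB in control, RGS4 had a slope of -0.931 log2 per hr, but BCL2A1 -0.115, SPOCD1 -0.06, CCL4 -0.083 and PCDH7 -0.068. Whether the emetine culture differed in these genes before the drug was not tested.

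In camera's test of levels in emetine, the immediate early list (adjusted p = 3.26e-13), the cholesterol list (0.000408), the mitotic list (0.000404; 14 of 29 higher), the splicing factor list (0.00214; 11 of 23 higher), the histone list (0.00893) and the p53 list (0.0135; 12 of 20 higher) rose and the oxidative phosphorylation list fell (0.0253; 7 of 42 lower). None of these held with an estimated correlation (adjusted p = 0.136 or more). Adjusted over the list alone, 33 immediate early genes passed upward. The 5601 calls became 2526 without the control array and 2672 without the emetine array at 0 hr. ATF4 lost its call in 7 of 8 fits without 1 array (highest adjusted p = 0.597), UPF1 in 3 (0.615), H2BC9 (0.66 ± 0.14) in 2 (0.199), SNHG4 in 2 (0.163) and H2BC12 (0.77 ± 0.12) in 1 (0.0557), among them the emetine array at 0 hr for all 5. UPF1 also lost its call with straight lines, with control and emetine arrays only, with no filter, after quantile normalization and with the median of its probe sets (adjusted p from 0.0534 to 0.277). The ACTB end ratio was 2.04 ± 0.19 (SD of 4 arrays) in emetine, against 0.55 ± 0.10 in control.

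After DRB, few transcripts fell in emetine relative to the array. Of transcripts that fell in depleted cells, the median slope was -0.22 in control and -0.003 in emetine, and 96.3% of the 2389 had a higher slope in emetine. Only 47 genes fell and 10 rose in emetine's own time course, against 2529 and 2063 in control. The slope differed from control for 1858 genes upward and 229 downward. Among the largest differences were those of transcripts lost fast in control: PLK2 (1.17 ± 0.13 log2 per hr, SE), TRMT10C (1.11 ± 0.07), SGK1 (1.08 ± 0.15) and MPHOSPH10 (1.07 ± 0.06). Of 43 immediate early genes 18 had a higher and 0 a lower slope, including BTG1 (0.65 ± 0.06), MCL1 (0.62 ± 0.07) and ZFP36L2 (0.62 ± 0.08). Of 14 NMD targets 8 had a higher slope: CEBPB (0.69 ± 0.07), MAP3K14 (0.55 ± 0.07), TBL2 (0.29 ± 0.04), ATF3 (0.61 ± 0.16), GADD45A (0.43 ± 0.12) and ATF4 (0.11 ± 0.03) among them. GADD45B (0.60 ± 0.21, adjusted p = 0.0747; 0.038 without the control array at 1.5 hr and 0.038 to 0.918 over the alternatives) and DDIT3 (0.13 ± 0.11) did not pass. Slopes were higher for 15 of 29 mitotic genes, 11 of 23 splicing factors and 9 of 20 p53 targets, and lower for 1 p53 target. EPB41L4A-AS1 (0.38 ± 0.07) and the histone H3C2 (0.35 ± 0.09) had higher slopes. LINC00942 (-0.51 ± 0.10), PSMD6-AS2, SEMA6A, MAP3K8 and FRMD3 had the lowest values, where LINC00942 and FRMD3 read 3.78 and 4.14 in control at 0 hr.

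The slope shifts of the immediate early (adjusted p = 1.09e-06), mitotic (1.24e-07), NMD target (0.000189), splicing (0.00473), integrated stress response (0.0212) and p53 (0.0387) lists passed camera's test upward and that of oxidative phosphorylation genes downward (0.0406). None held with an estimated correlation (adjusted p = 0.566 or more). Adjusted over the list alone, 23 immediate early, 21 mitotic and 10 NMD target genes passed. The 2087 calls became 967 and 1376 without the control array at 0 and 4.5 hr, and 1173 and 1133 without those of emetine. ATF4 lost its call in 8 of 8 fits without 1 array (highest adjusted p = 0.357), GADD45A in 5 (0.674), ATF3 in 3 (0.397; control at 0 hr, emetine at 0 or 4.5 hr), and EPB41L4A-AS1 without the control array at 0 hr (0.0684). H3C2, LINC00942, MAP3K8, FRMD3 and SEMA6A lost theirs in 2 to 5. Without the control array at 0 hr the slope differences were 0.71 for SGK1, 0.34 for ATF3, 0.20 for EPB41L4A-AS1, 0.11 for GADD45A and -0.11 for FRMD3, and without that at 4.5 hr 0.92 for ATF3, 0.23 for H3C2, -0.65 for SEMA6A and -0.72 for FRMD3. They were -0.68 for SEMA6A and -0.24 for MAP3K8 without the emetine array at 0 hr, and 0.18 for H3C2 and -0.28 for SEMA6A without that at 4.5 hr. SEMA6A had 0.02 with the median of its probe sets.

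In UPF1-depleted cells more transcripts had a higher than a lower level relative to control, 1401 against 577. The size of this excess depended on how the arrays were scaled. Among 14 NMD target transcripts, 9 rose and 0 fell: ATF3 5.91-fold (2.56 ± 0.44, SE), GADD45B 5.02-fold (2.33 ± 0.58), GADD45A 2.43-fold (1.28 ± 0.34), DDIT3 2.36-fold (1.24 ± 0.32), NAT9 1.70-fold (0.76 ± 0.12) and ATF4 1.51-fold (0.59 ± 0.10). The measured differences of the arrays at 0 hr were smaller for ATF3 (1.89), GADD45B (1.38) and GADD45A (0.73) than these fitted ones, where the lines cover 4.5 hr and these transcripts fell mostly within 1.5 hr in control cells. The snoRNA hosts EPB41L4A-AS1 (4.67-fold; 2.23 ± 0.19) and ZFAS1 (1.74-fold; 0.80 ± 0.09) rose, 2 of 4 measured hosts, and SNHG4 had 0.41 ± 0.18 (adjusted p = 0.15; 0.0176 without the depleted array at 1.5 hr). Without the control array at 0 hr the log2 differences were 3.50 for ATF3, 3.72 for GADD45B, 2.39 for GADD45A and 2.87 for EPB41L4A-AS1, and without the depleted array at 0 hr 3.58 for ATF3, 3.69 for GADD45B and 1.89 for TCIM. Of 8 NMD factors 3 rose, among them SMG9 (1.71-fold) and SMG6 (1.53-fold), which act with UPF1, and 1, UPF1 itself, fell. Of 34 integrated stress response genes 8 rose and 0 fell. The highest other estimates were those of ZFAND2A, a heat- and arsenite-inducible gene (6.06-fold; 2.60 ± 0.14), the stromelysin MMP3 (4.82-fold) and TCIM (2.54 ± 0.30), whose control signals, log2 2.90 to 4.44, lay below the filter value of 4.70. ODAPH (-2.39 ± 0.20), PCDH9 (-1.99 ± 0.12), KRT75 (-1.98 ± 0.18), MMP9 (-1.86 ± 0.14) and NRXN3 (-1.74 ± 0.13) were lowest. In depleted cells ODAPH read log2 4.15 to 4.52 and PCDH9 4.64 to 5.10, around or below the filter value, so both sizes are uncertain. At 0 hr MMP9 read 11.94 in control and 11.79 in tunicamycin, against 10.31 in hypoxia, 9.92 in emetine and 10.02 in depleted cells. KRT75 (lower) and MMP3 (higher) grouped the conditions in the same way, as did the ACTB end ratio. None of 23 splicing factors and none of 18 interferon-stimulated genes passed, with SRSF6 at 0.28 ± 0.11 and IFIT2 at -0.53 ± 0.21 (adjusted p = 0.115; 0.0424 without the depleted array at 3 hr). Of 13 mesenchymal genes 4 fell.

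For levels in depleted cells, camera's test (limma) passed upward for the NMD target (adjusted p = 8.67e-07), integrated stress response (1.36e-06), snoRNA host (0.00356), immediate early (0.0211; 6 of 43 higher) and p53 (0.0286; 6 of 20 higher) lists and downward for the mesenchymal list (0.00356). With an estimated correlation the integrated stress response list held (adjusted p = 0.0171) and the NMD target list did not (adjusted p = 0.0914), nor did the others (adjusted p = 0.139 or more). Adjusted over the list alone, 12 NMD targets and 13 integrated stress response genes passed. The 1978 calls became 318 without the control array and 274 without the depleted array at 0 hr. The share of calls that were higher, 70.8%, was 53.5% when arrays were centred on ribosomal protein genes and 51.7% after quantile normalization, where SMG6 had an adjusted p of 0.0505. Without 1 array, calls were lost for GADD45A (5 of 8 fits; highest adjusted p = 0.113), GADD45B (3; 0.0646), DDIT3 (6; 0.199), ATF4 (2; 0.0741), SMG6 (3; 0.124) and SMG9 (2; 0.144), whereas those of ATF3, NAT9, EPB41L4A-AS1 and ZFAS1 passed in all 8. The ACTB end ratio was 1.24 ± 0.06 (SD of 4 arrays) in depleted cells.

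After DRB, few slopes differed between depleted and control cells: RSRC2 (0.37 ± 0.05 log2 per hr, SE), ZNF75A (0.31 ± 0.04), ZNF232 (0.27 ± 0.03), SLC19A2, a thiamine transporter (0.26 ± 0.04), and ORC6, a subunit of the replication origin complex (0.25 ± 0.04), had higher slopes, and EFNA2, an ephrin, a lower one (-0.47 ± 0.05), with adjusted p from 0.0169 to 0.0306. None of the 14 NMD targets passed over the whole time course: MAP3K14 had 0.27 ± 0.07, ATF3 0.31 ± 0.16, GADD45A 0.07 ± 0.12, GADD45B -0.14 ± 0.21, DDIT3 -0.24 ± 0.11, TBL2 0.08 ± 0.04 and ATF4 0.06 ± 0.03. EPB41L4A-AS1 had 0.29 ± 0.07 (adjusted p = 0.257). Among transcripts chosen because they fell in hypoxia (2049 genes), the median slope in depleted cells was 93.3% of that in control. At an unadjusted p under 0.05 there were 955 genes, and the 6 calls became 0 without the 0 hr or the 4.5 hr array of either condition and 3 without the depleted array at 1.5 hr, but 10 with either filter at the 60th percentile and 29 with trend and robust eBayes. ORC6 had an adjusted p of 0.0779 after quantile normalization. The cholesterol (adjusted p = 0.0406) and mitotic (0.0467) lists passed camera's test upward with 0 members past the test, and neither held with an estimated correlation (adjusted p = 0.679 and 0.715).

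A line over 4.5 hr hides the first interval, because GADD45A and GADD45B had reached a plateau in control cells by 1.5 hr, with changes of 0.04 and 0.02 from then to 4.5 hr. The change from the 0 hr to the 1.5 hr array was therefore also read, a measure chosen after seeing the data and without a replicate or a test. ATF3 changed by -1.73 in control, -1.07 in hypoxia, -0.49 in emetine, -0.11 in tunicamycin and -0.02 in depleted cells. GADD45A changed by -1.93 in control, -1.38 in hypoxia, -0.56 in depleted cells, -0.11 in tunicamycin and -0.06 in emetine. GADD45B changed by -2.99 in control, -2.50 in hypoxia, -2.06 in tunicamycin, -1.04 in depleted cells and -0.29 in emetine. DDIT3 showed little such difference in depleted cells and the opposite in hypoxia. It changed by -0.45 in control, -0.72 in hypoxia, -0.40 in depleted cells, -0.30 in tunicamycin and -0.24 in emetine. EPB41L4A-AS1 changed by -1.21 in control and between -0.39 and -0.08 in the other conditions. Over the 14 NMD targets the median change was -0.51 in control, -0.32 in hypoxia, -0.17 in depleted cells and -0.11 in both tunicamycin and emetine. Of the 14, 10 in depleted cells, 11 in hypoxia, 12 in tunicamycin and 13 in emetine changed less negatively than in control. Those that did not in depleted cells were ASNS (0.22 in control, -0.04 in depleted cells), SLC7A11 (0.08, 0), CARS1 (-0.18, -0.19) and UPP1 (-0.03, -0.05). Immediate early transcripts changed by a median of -1.60 in control, -0.91 in hypoxia, -0.84 in tunicamycin, -0.72 in depleted cells and -0.21 in emetine. Every such difference from control uses the same pair of control arrays. From 1.5 to 4.5 hr ATF3, GADD45A, GADD45B and DDIT3 changed by -0.97, 0.04, 0.02 and -0.16 in control. In depleted cells they changed by -1.38, -0.85, -2.31 and -1.22, so a smaller early change was followed by a larger later fall. In tunicamycin the values were -0.67, -0.34, -2.48 and -2.44. They were -0.83, -0.32, 1.14 and 0.89 in hypoxia and 0.35, 0.25, 0.16 and 0.21 in emetine.

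**Figure D4:**
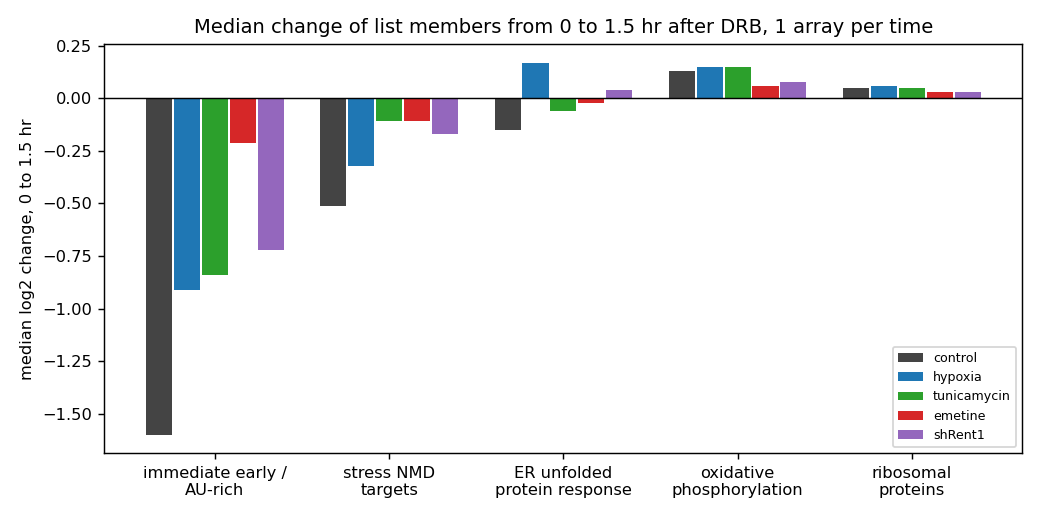
Median log2 change from 0 to 1.5 hr after DRB (vertical axis) of the members of 5 gene lists, 1 bar per condition from 1 array per time and so without error bars. Immediate early transcripts change by -1.60 in control and -0.21 in emetine, and ribosomal protein transcripts by 0.03 to 0.06 in all 5 conditions.

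Slopes were also compared between conditions directly. They differed for 1986 genes between emetine and depleted cells, 1912 between hypoxia and emetine, 927 between tunicamycin and emetine, 855 between hypoxia and tunicamycin, 491 between tunicamycin and depleted cells and 15 between hypoxia and depleted cells (limma, adjusted p under 0.05). The slope of XBP1 was higher in tunicamycin than in depleted cells (0.63 ± 0.11 log2 per hr, SE; adjusted p = 0.00877) and than in hypoxia (adjusted p = 0.0397). That of CHAC1 was lower in tunicamycin than in hypoxia, emetine and depleted cells (highest adjusted p = 0.00877). GADD45B had a higher slope in emetine than in depleted cells (0.74 ± 0.21, adjusted p = 0.0305), and ATF3 did not differ past the test between any pair (lowest adjusted p = 0.0772).

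Because all comparisons share the 4 control arrays, likeness between them was set against simulated unchanged groups. Across genes, which are not independent replicates, slope differences in depleted cells correlated with those in hypoxia at 0.376, in tunicamycin at 0.435 and in emetine at 0.32, against simulated values of 0.499, 0.497 and 0.5. The covariances were 0.00176, 0.00271 and 0.00297, against simulated values of 0.00154, 0.00154 and 0.00155. With the control arrays split by time the correlations were -0.18, 0.0393 and 0.0752. Of the 5 transcripts with a higher slope in depleted cells, 4 also had one in tunicamycin and 5 in emetine (0.233 and 0.642 for independent lists) and 0 in hypoxia. Lists that share control arrays are not independent, here and for the levels below. In the simulated unchanged groups the highest joint count was 0 for slopes and for levels. Neither value says what overlap shared controls give among called genes, so a shared effect cannot be read from these counts. For levels, 124 genes were higher in both depleted cells and tunicamycin (27.6 for independent lists), 112 in depleted cells and hypoxia (45.0) and 630 in depleted cells and emetine (265). Genes lower in both numbered 34 (5.34), 96 (25.6) and 291 (114), and those called in opposite directions 14, 63 and 187. Level covariances were 0.0353, 0.0233 and 0.0858 against simulated 0.0122, 0.0121 and 0.0122, and correlations were 0.363, 0.224 and 0.415 against 0.498, 0.499 and 0.501. With no array in common, correlations of mean level differences were 0.36, 0.169 and 0.412.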

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

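The tests on the signal floor, on genes raised or lowered by tunicamycin, on a control culture that stands apart and on 0 hr arrays of the conditions left out were chosen only after the results were seen. Among 35 sets of 4 arrays (5 array measures and 2 UPF1 probe sets per condition), 1 held a value far from the rest. Chance flags about 1 set in 20, so 1 flag among 35 is no more than chance gives. The brighter UPF1 probe set in depleted cells read 169.5 at 0 hr and 89.4 to 94.7 afterwards. The dimmer did not stand out, with 68.0 at 0 hr and 58.1 to 85.2 afterwards. The slopes of 855 genes differed between hypoxia and tunicamycin, 1912 between hypoxia and emetine, 15 between hypoxia and depleted cells, 927 between tunicamycin and emetine, 491 between tunicamycin and depleted cells and 1986 between emetine and depleted cells.

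The 3' to 5' signal ratio of ACTB, from control probe sets that no comparison used, averaged 2.04 on the log2 scale in hypoxia, 2.04 in emetine and 1.24 in depleted cells, above the control range of 0.44 to 0.65. The GAPDH ratio averaged 0.15, 0.11 and 0.07 against 0.04 in control. A rise of HIF targets or immediate early genes produced by such a bias is argued against by conditions with alike ratios: HIF targets had a median of 0.858 in hypoxia minus emetine (1.20 against control) and immediate early genes 2.20 in emetine minus hypoxia (2.76 against control). A general 3' bias of the hypoxia and emetine arrays stays open, since within-gene deviations of probe sets correlated at 0.157 between hypoxia minus tunicamycin and emetine minus control, which share no array (highest of 200 shuffles 0.045), over 7055 genes. RNA handling, array batch and condition cannot be told apart here, because each ratio belongs to a whole condition, so single level calls in these 3 conditions may hold a technical part.

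At DRB addition, 24 genes were higher and 10 lower in all 4 conditions than in control, against 0.167 and 0.0469 for independent lists. Noise of the shared control arrays stays open: 20 simulated sets of unchanged groups gave at most 0 such genes, but each held a comparison with 0 calls, so no other count was possible. A single aberrant control array stays open: without the control array at 0 hr the 34 became 8, of which 2 were among the 34, the fall that such an array would give, but leaving out the 0 hr array of a condition gave 5 for tunicamycin, 10 for hypoxia, 16 for depleted cells and 25 for emetine, so a fall as large came from 1 of these 4 arrays. A control culture that stood apart cannot be told apart from a response shared by the 4 conditions, as no second control exists. As the reference, tunicamycin gave 83 such genes, hypoxia 219, depleted cells 558 and emetine 2192. The 34 with control as the reference were thus the fewest. The shared response is an untested hypothesis.

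The 84 transcripts with a more negative slope in tunicamycin than in control include DDIT4, CHAC1, SESN2 and DDIT3. A control mean near the signal floor, as the whole cause, is argued against, since 61 of the 84 were still called among genes whose control mean lay above the 60th percentile. A first measure, seen before this one replaced it, had 25% of the 84 below that percentile in control at 0 hr, against 24.7% of all genes tested. A floor reached only late in control stays open, because a mean over the times does not exclude it. DDIT4, for example, read log2 7.72 at 0 hr and 4.82 at 3 hr in control. A fall from a level that tunicamycin had raised, as the whole cause, is argued against too: 10 of the 84 were called lower at DRB addition and 43 (51.2%) had a higher estimate. For the 22.6% that were called higher, against 1.97% of all genes tested, it stays open, because level and slope come from the same fit and their errors are linked.

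Swapping control and condition arrays within time points gives 8 splits per comparison, too few for a share under 0.05. For levels, the real count and the highest other were 1108 and 1246 in hypoxia (2 of 8 as large), 419 and 23 in tunicamycin (1 of 8), 5601 and 4835 in emetine (1 of 8), and 1978 and 1526 in depleted cells (1 of 8). For slopes they were 5 and 2771, 758 and 2688, 2087 and 8073, and 6 and 3747, with 3 of 8 splits as large in each. The highest split for slopes swapped 3 and 4.5 hr, which turns a level difference between conditions into a slope, so these large counts point to the conditions' level differences.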

How the results depend on the processing

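The filter on control means above the 60th percentile, the added list members and the alternatives for slopes between conditions were chosen only after the result was seen; the others were fixed before. The replicate numbers are time points, which the model takes as a factor, with 1 array per condition and time. Across the alternatives, list tests kept side and direction 538 times, 49 lost and 5 gained the threshold and 0 reversed; genes named in the comparisons did so 3750 times, 398 lost, 47 gained and 8 reversed. The reversals came with the median of a gene's probe sets (ZBED5 0.05 and NDUFB1 -0.093 for control slopes, HERPUD1 -0.172 for the slope in tunicamycin, SEMA6A 0.021 for that in emetine, TMEM165 0.073 for the level in tunicamycin) and without _x_at and _s_at probe sets (ZBED5 0.139, NDUFB1 -0.293, HERPUD1 -0.534); the cause was not tested. Control slopes numbered 1582 from the control arrays alone, 1375 without the 0 hr and 1931 without the 4.5 hr arrays. Slope calls in hypoxia (5) became 0 with straight lines, 0 with control and condition only, 0 centred on ribosomal protein genes, 0 with median probe sets, 0 without the 4.5 hr arrays, 1 without the 0 hr arrays, 1 after quantile normalization, 1 without _x_at and _s_at probe sets, 24 with the filter at the 60th percentile, 25 with that on control means and 54 with trend and robust eBayes. In tunicamycin (758) they became 468 with straight lines, 266 with control and condition only, 501 with median probe sets, 484 without _x_at and _s_at probe sets, 23 without the 0 hr and 141 without the 4.5 hr arrays. In emetine (2087) they became 1296 with control and condition only, 618 without the 0 hr and 933 without the 4.5 hr arrays. In depleted cells (6) they became 1 with straight lines, 0 with control and condition only, 10 with either filter at the 60th percentile, 29 with trend and robust eBayes, and 0 without the 0 hr or 4.5 hr arrays. Level calls with control and condition only numbered 130 in hypoxia, 130 in tunicamycin and 768 in depleted cells; without the 4.5 hr arrays 351, 133 and 869; as the mean over the 4 times 2883, 3260 and 4540, and 9246 in emetine. Levels in hypoxia numbered 688 without _x_at and _s_at probe sets, and in tunicamycin 234 with straight lines and 683 with trend and robust eBayes. Between conditions, straight lines gave 421 slopes for hypoxia and tunicamycin, 1 for hypoxia and depleted cells, 562 for tunicamycin and emetine and 223 for tunicamycin and depleted cells; hypoxia and depleted cells gave 42 with the filter at the 60th percentile and 7 centred on ribosomal protein genes. With control arrays split by time, slope correlations with depleted cells were -0.18 in hypoxia, 0.0393 in tunicamycin and 0.0752 in emetine, where the sets of control arrays cover different times. With GARS1 and SARS1 added to the integrated stress response list (36 measured) and COXFA4 to the oxidative phosphorylation list (43), no call of either list for levels or slopes against control changed; in hypoxia 4 of the 36 were lower. Fewer arrays lower precision by construction; for the other settings the cause was not tested. Leaving out 1 array gave 1492 to 4878 control slopes; slope calls of 0 to 7 in hypoxia, 141 to 705 in tunicamycin, 967 to 2099 in emetine and 0 to 6 in depleted cells; and level calls of 77 to 1163, 88 to 414, 2526 to 5671 and 274 to 1981.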

Other observations

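The test of early loss below was chosen only after the result was seen. Genes higher in all 4 conditions included PTGS2, the inducible cyclooxygenase (log2 1.57 in hypoxia, 2.73 in tunicamycin, 4.21 in emetine and 1.05 in depleted cells), LPIN1, a lipid phosphatase (0.49, 0.52, 1.77 and 1.76), NUPR1, a stress-induced nuclear protein (0.39, 1.07, 0.53 and 1.98), AGO4, an Argonaute protein (0.60, 0.87, 1.27 and 1.47), and KDM7A, a histone demethylase (1.10, 1.77, 1.55 and 1.36). Those lower in all 4 included ODAPH (-2.56, -1.64, -2.66 and -2.39), CCL4 (-1.99, -0.55, -2.94 and -1.04), CCL2 (-0.82, -1.19, -2.08 and -1.22) and THY1, a surface glycoprotein (-0.94, -0.61, -1.36 and -0.93). ODAPH read log2 4.27 to 4.77 in hypoxia, 4.05 to 4.42 in emetine and 4.15 to 4.52 in depleted cells. These signals lay around or below the filter value of 4.70, so the sizes of its differences are uncertain. All the genes named in this paragraph passed the limma test in each condition, share the same control arrays and were chosen after their values were seen.

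Heat shock genes had 2 of 14 lower in hypoxia, 1 lower in tunicamycin, 2 higher in emetine and 0 called in depleted cells at DRB addition. Interferon-stimulated genes had 1 of 18 higher in hypoxia, and 5 higher and 2 lower in emetine. Ribosomal protein transcripts had 0 of 51 called in any of the 4 levels or 4 slopes. Markers of other cell types had 0 of 11 called for levels in hypoxia, tunicamycin and depleted cells and 2 lower in emetine. In the first 1.5 hr after DRB, members of the ER list changed by a median of -0.15 in control, 0.17 in hypoxia, -0.06 in tunicamycin, -0.02 in emetine and 0.04 in depleted cells, and histone genes by 0.24, 0.25, 0.02, -0.07 and 0.14, each from single arrays.

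A hypothesis from these data is that stress transcripts that are NMD targets may be lost more slowly than in control in the first 1.5 hr after DRB in depleted cells and after tunicamycin, emetine or hypoxia. Replicate arrays between 0 and 1.5 hr would decide it. Their median change relative to control was 0.26 in depleted cells, 0.33 in tunicamycin, 0.45 in emetine and 0.30 in hypoxia. Among 10000 random lists matched on mean signal, the lowest percentile over the first 3 was 100, rounded, and hypoxia lay at the 99.99th percentile. This comparison uses the arrays that prompted the hypothesis and does not measure the scatter between single arrays, so it describes them and does not test it. Immediate early genes lay at the 100th percentile in all 4 conditions too, ER genes between 96.31 and 100 and the 4 snoRNA hosts between 97.65 and 99.97, so the shift was not particular to NMD targets. All these values rest on the same pair of control arrays at 0 and 1.5 hr, and an unusual control array at either time stays open.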
